A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

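Total RNA of budding yeast was compared on 11 Agilent whole-genome arrays with 2 colours. Of these, 5 held RNA of strains that each lacked 1 histone chaperone gene (ASF1, CHZ1, NAP1, RTT106 or VPS75), 5 held RNA of the same strains after trichostatin A (TSA), and 1 held RNA of the parent BY4742 after TSA. TSA inhibits histone deacetylases. Per the labels, cells grew at 30 °C in rich glucose medium, and cultures for TSA reached an optical density of 0.5 and were treated with 10 µM for 1 hour. The density and added time of the untreated cultures were not given in the sources used here. Per the labels, the reference was labelled with Cy5 and the experimental RNA with Cy3, and no dye was swapped. The sample descriptions name wild type as the reference.

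The authors deposited, for each array, the intensity of both channels in 2 repeat measurements of every probe, a merged intensity per channel, their log10 ratio and a signed fold rounded to 1 decimal. The series matrix, deposited by the authors as log2 values, equalled the log2 of that rounded fold within 4.9e-05. Its columns were not centred. Their medians were 0, except for the array of the asf1 deletion with TSA at −0.138. Because of the rounding, 20.8% to 51.9% of the values in a column were exactly 0. The matrix columns of the 2 vps75 arrays held each other's file, and the sample files were followed here. The scanner settings, the background correction and the scaling between channels that preceded these values were not given in the sources used here. The deposited ratios ran as reference over experimental RNA on all arrays but that of the nap1 deletion without TSA. All values here are experimental over reference, the opposite of most deposited columns.

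The direction of each array was read from its deleted gene. On the nap1 array without TSA, NAP1 was low in the column that held the reference elsewhere, and the array was turned. The wild type array lacks a deleted gene, and its direction is only likely. On that array the floor signal of the experimental column was 2.06 times that of the reference column, and on the other arrays the ratio lay between 1.72 and 5.47. The labels disagree on the reference of the deletion arrays with TSA and of the chz1 array without TSA, since their channel 1 entries name the untreated deletion strain. By a rule fixed earlier, the wild type reading held unless the deleted gene was missing from the reference channel. It was detected there on 10 of 10 arrays, so wild type was taken as the reference throughout.

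Each signal was raised by 50, log2 ratios were normalized by loess within each repeat measurement, and the 2 measurements were averaged, with limma 3.58.1 in R 4.3.3. The planned background correction needed a background column, which the files did not hold. The planned scanner flags were likewise replaced, and a gene counted as detected where its signal exceeded 2 times the median of URA3, LEU2, HIS3 and LYS2, which are deleted from BY4742. Every gene had 1 probe. Of 6256 genes, 5756 were matched by systematic name to the RefSeq table of assembly R64 for their symbols, and 500 were not. A gene entered the fits if it was detected in either channel on at least 50% of the arrays of the deletion strains, which left 5916 genes. Control probes were left out, 18 on the chz1 array without TSA and 0 on the others.

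The TSA effect was fitted by lmFit and eBayes on the 10 arrays of the deletion strains, with strain as a block and Benjamini-Hochberg adjustment at 0.05. Strain pairs the arrays by design. The correlation of the deviations within a pair, across genes, was 0.59 for asf1, −0.15 for chz1, 0.40 for nap1, 0.66 for rtt106 and 0.68 for vps75. Each deletion was contrasted with the mean of the other 4 in the same fit. A strain's 2 arrays may share a culture, which can make the spread of these contrasts too small. The wild type array and the 5 arrays without TSA have no replicate, and genes at least 2-fold higher or lower were counted with no p-value. Bootstrap intervals of the subtelomeric shift on single arrays used 2000 resamples of the genes and cover no spread between cultures.

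Before the data were examined, 38 gene lists were fixed, among them histones, silencing factors, stress, metabolic, cell cycle and cell wall genes. They were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. On single arrays a list's median was set among 10000 random lists of equal size, matched on mean signal in 20 bins. Subtelomeric genes were the 10 outermost systematic names of each of 32 chromosome arms, because no coordinates were used. They were tested by an exact two-sided sign-flip test over the strains.

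Named genes followed a rule set at the same time. For TSA across the deletions it took up to 12 genes in each direction, by adjusted p and the same sign in all 5 strains, and filled up by smallest p where fewer passed. It took the 6 highest and lowest genes on the wild type array, 3 in each direction on each deletion array and in each contrast, the deleted genes, and up to 4 members per list. In the contrasts, members past the threshold were named, chosen by size. Genes without a standard name or a RefSeq entry were skipped, of which the TSA comparison had 4.

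The fits, the list test and the subtelomeric test were tested on simulated data with the noise of these arrays. In the TSA fit 76.1% of genes changed by 0.5 on the log2 scale were recovered, 98.5% at 1 and 100% at 2, with 5 unchanged genes called among 5916. In another run every gene had the same noise, the median left after removal of the chz1 pair, and all 5 strains stayed in the fit. There 100% were recovered at 0.5, with 14 unchanged genes called. This does not give the recovery of a fit without that pair, or of genes noisier than the median. The strain contrast recovered 34.3% at 0.5, 92.5% at 1 and 100% at 2, with 9 unchanged genes called. The list test found the 1 list that had been moved by 0.5 and called 2 others. Subtelomeric genes were lowered in the same simulated data, so lists that hold such genes had moved too, and the 2 are not plain false calls. The noise was drawn for each gene apart, so the correlation between genes was not tested. A subtelomeric shift of −0.3 was recovered, with an exact two-sided p of 0.063, the smallest that 5 strains allow. With 1 array per strain and treatment, the number of arrays limits the precision of all values.

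Alternatives covered the background correction, the normalization within and between arrays, the deposited log ratios, the detection filter, the reading of the reference, the direction of single arrays, the block, the strains included, the variance model, the fold threshold and the definition of subtelomeric genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.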

Results

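Transcript levels were measured for 6256 genes of budding yeast on 11 arrays. The strains lacked Asf1, Chz1, Nap1, Rtt106 or Vps75, all of which are histone chaperones, proteins that hand histones to or take them from DNA. Each of the 5 deletions was measured once without and once with the histone deacetylase inhibitor TSA, and the wild type once with TSA, always against RNA that was read here as untreated wild type. There were no replicates of any strain and treatment. The p-values of the TSA comparison rest on the 5 strains as replicates, and those of the strain contrasts on the 2 arrays of a strain, with and without TSA, which may share a culture. Both measure only the spread between these arrays. Median signals lay between 357 and 1095 per channel, and the 2 repeat measurements of an array correlated across genes at 0.838 (nap1 with TSA) to 0.975 (rtt106 with TSA).

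The deleted genes were the first check of the labels. Ratios are experimental over reference RNA, the opposite of most deposited columns. ASF1 (YJL115W) had a log2 ratio of −4.47 without and −3.68 with TSA in its own strain. CHZ1 (YER030W), which encodes a chaperone of the histone variant H2A.Z, stood at −2.86 and −4.06. NAP1 (YKR048C) stood at −3.31 and −4.53, RTT106 (YNL206C) at −3.25 and −3.34, and VPS75 (YNL246W) at −3.94 and −3.70. On the 45 combinations of these genes with arrays of other strains, ratios stayed between −0.39 and 0.386. In the reference channel of their own strain's arrays the deleted genes had a signal of at least 719, on arrays with and without TSA. The array labelled chz1 deletion without TSA thus held a strain with low CHZ1, although its labels name a treatment in one field and glucose in another.

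**Figure D1:**
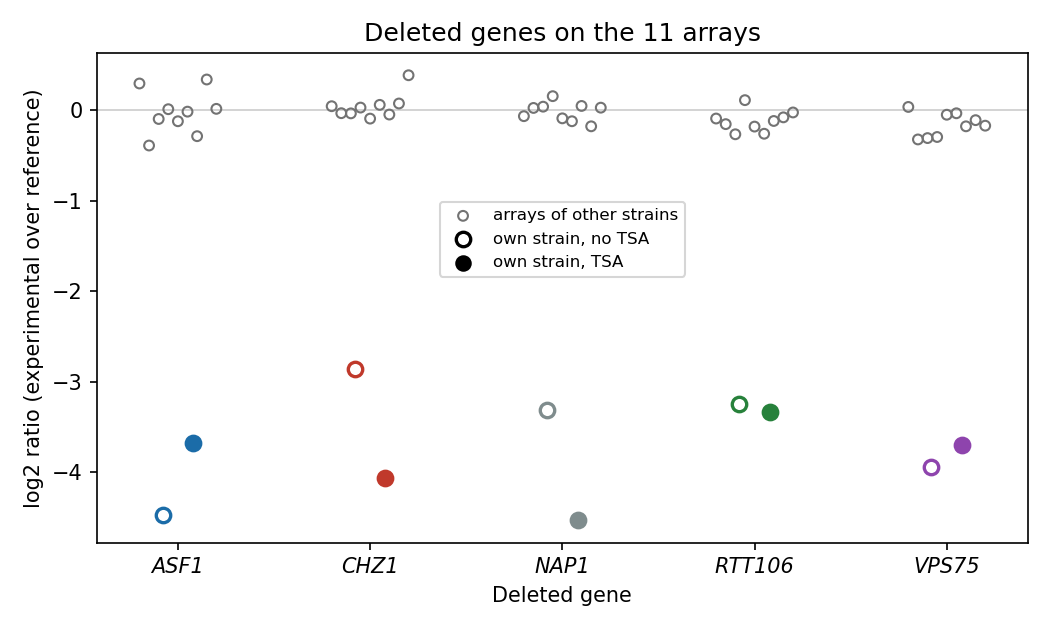
Log2 ratio of each deleted gene on every array, experimental over reference RNA. Points of a gene's own strain lie between −4.53 and −2.86, and those of all other arrays between −0.39 and 0.386.

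The main question was which genes respond to TSA in cells that lack a chaperone. The smallest p was found for BSC1 (YDL037C), with a mean log2 difference of −0.96 (SE 0.108, 5 of 5 strains). CTR1 (YPR124W), the high-affinity copper transporter, averaged −1.15 (SE 0.234), and FRE1 (YLR214W), a metalloreductase of the cell surface, −1.48 (SE 0.435), or −0.94 without the chz1 pair, both below 0 in 5 of 5 strains. The copper transporter gene CTR3 stood at −0.42, REE1 at −0.79 and IRC7 at −0.69. Higher values in 5 of 5 strains were found for the cell wall mannoprotein gene CWP2 (0.57, SE 0.089) and for GPP2 (0.58, SE 0.093), which makes glycerol from glycerol phosphate. No single gene passed the adjustment.

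The other genes named on the higher side were glycogenin GLG1 (0.49), glycogen synthase GSY1 (0.56), phosphoglucomutase PGM2 (0.41) and GPM2 (0.76, or 0.50 without the chz1 pair). The glucan synthase gene GSC2 stood at 0.59 and ROM1, an exchange factor for the GTPase Rho1, at 0.56. Cytochrome c CYC1 (0.58), the mitochondrial elongation factor TUF1 (0.29), the vacuolar calcium pump gene PMC1 (0.34) and TFS1 (0.45) completed this side. On the lower side stood EPL1 (−0.32), a subunit of the NuA4 histone acetyltransferase, and SAS5 (−0.29), a subunit of the SAS acetyltransferase that acts at silenced chromatin. The drug efflux pump gene PDR5 stood at −0.41, carbonic anhydrase NCE103 at −0.70 with 4 of 5 strains below 0, and RRP12 (−0.41) and TRF5 (−0.27) act on ribosome assembly and RNA surveillance. In wild type cells with TSA, CWP2, GPP2, CTR1, FRE1 and REE1 had ratios of 0.51, 0.61, −1.03, −1.68 and −1.40, whereas BSC1 (0.28) and PDR5 (0.58) went the other way.

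Of 5916 genes, limma called 0 for TSA across the 5 strains, with a smallest adjusted p of 0.22 for BSC1, then 0.747 for CWP2 and GPP2 and 0.814 for the other named genes. At an unadjusted p under 0.05 there were 254 genes, 142 higher and 112 lower, where chance gives 296. The sign was the same in all 5 strains for 473 genes (8.0%, 6.25% by chance), 244 higher and 229 lower, and 331 of these had it in wild type too, or 142 with the wild type array turned, whose direction is only likely. Had the untreated deletion strain been the reference, as the channel labels have it, limma would have called 202 genes higher and 206 lower, but the signal of the deleted genes in the reference channel speaks against that reading.

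**Figure D2:**
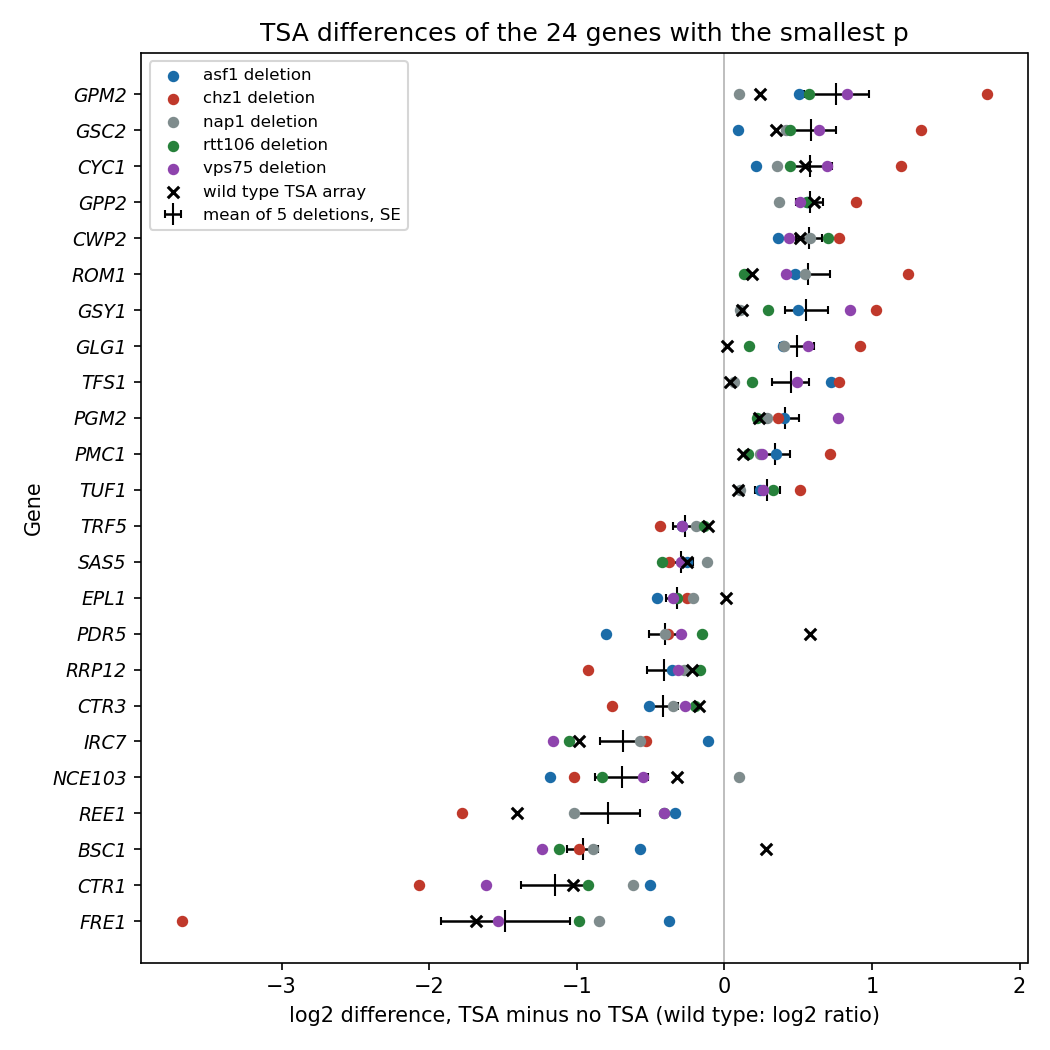
TSA minus no TSA log2 difference of the named genes in each of the 5 deletion strains, with the mean and its SE, and the wild type ratio. CTR1 and FRE1 lie below 0 in every strain, and the chz1 deletion reaches −3.68 for FRE1.

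Gene lists gave larger groups that stood apart from the rest of the genes under TSA, but only in a test that presets the correlation between genes (camera). List medians and member counts are of the genes' means over the 5 strains. Counts of strains give how many had a list median of their own on that side of 0. Ribosome biogenesis genes were lower, with 72 of 73 below 0 and a median of −0.26, below 0 in 4 of 5 strains (preset adjusted p = 2.2e-16, adjusted p = 0.75 with an estimated correlation). Strain medians were −0.94 in chz1, −0.22 in asf1, 0.11 in nap1, −0.03 in rtt106 and −0.17 in vps75. Without the chz1 pair the list median was −0.08 (preset adjusted p = 0.00014). The members LTV1 (−0.48), MRD1 (−0.45), NOP15 (−0.45) and NSR1 (−0.42) then stood at −0.18, −0.16, −0.21 and −0.11. Respiratory chain genes were higher, 35 of 35 above 0 with a median of 0.28, above 0 in 5 of 5 strains (preset adjusted p = 4.4e-11, adjusted p = 0.75 with an estimated correlation). Here chz1 had 1.19, against 0.06 in asf1, 0.09 in nap1, 0.04 in rtt106 and 0.15 in vps75. Without chz1 the list stood at 0.06 (preset adjusted p = 0.00022), CYC1 at 0.43 and SDH1 at 0.17, against 0.58 and 0.54 with it. Proteasome genes were lower, with a median of −0.16, below 0 in 4 of 5 strains (preset adjusted p = 8.9e-09, adjusted p = 0.75 with an estimated correlation). In chz1 their median was −0.40, against 0.02 in asf1, −0.07 in nap1, −0.11 in rtt106 and −0.07 in vps75. Without chz1 the list stood at −0.06 (preset adjusted p = 0.0055), while RPT1 went from −0.25 to −0.09.

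Stress-induced genes were higher (50 genes, median 0.15, 4 of 5 strains, preset adjusted p = 1.6e-06, adjusted p = 0.75 with an estimated correlation), with 0.16 without the chz1 pair. The test turned with the series matrix, which also exchanges the vps75 arrays (median 0.04, adjusted p = 0.82). The members of the stress list rested more on the chz1 pair. Glycogen phosphorylase GPH1 averaged 1.03, the stress activator MSN4 0.87 and the trehalose synthesis gene TSL1 0.80, and without chz1 they stood at 0.70, 0.45 and 0.48. Cell cycle genes of G2 and M had a median of 0.15, above 0 in 4 of 5 strains (preset adjusted p = 1.6e-06, adjusted p = 0.75 with an estimated correlation), and 0.09 without chz1, where WSC4 stood at 0.68 in place of 1.29 and the cyclin CLB1 at 0.55 in place of 1.00. Phosphate regulon genes had a median of 0.11, above 0 in 5 of 5 strains (preset adjusted p = 0.0042, adjusted p = 0.75 with an estimated correlation), and 0.06 without chz1 (preset adjusted p = 0.028), with acid phosphatase PHO5 at 1.00 and 0.57. Nitrogen catabolite repressed genes stood at 0.10, above 0 in 4 of 5 strains (preset adjusted p = 0.0042, adjusted p = 0.75 with an estimated correlation), and at 0.03 without chz1 (preset adjusted p = 0.028). Their permease gene AGP1 averaged 0.85 with 3.35 in chz1, and 0.23 without it, and GAP1 0.59 and 0.28. Sulfur and methionine genes stood at −0.10, below 0 in 4 of 5 strains (preset adjusted p = 0.005, adjusted p = 0.75 with an estimated correlation), and at −0.08 without chz1. They turned with the series matrix and its exchanged vps75 arrays (median 0.03, adjusted p = 0.86). MET14 averaged −0.68, or −0.39 without chz1.

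Heat shock genes (median −0.20, adjusted p = 0.005, 4 of 5 strains), the iron regulon (−0.24, adjusted p = 0.0036, 3 of 5 strains) and phospholipid genes (0.11, adjusted p = 0.026, 4 of 5 strains) passed the preset test only with the chz1 pair. Without it their adjusted p were 0.28, 0.40 and 0.23, and with an estimated correlation all 3 were lost (adjusted p = 0.83 for heat shock and 0.75 for the others). Within these lists BTN2 averaged −1.27, with −4.26 in the chz1 strain and a mean of −0.52 without it, and FIT2, a cell wall protein that retains iron carriers, averaged −0.66, or −0.39 without it. In the chz1 strain the iron regulon had a median of −0.79 and heat shock genes −0.56. Lists that did not pass included silencing factors (median −0.03, 11 of 13 below 0, adjusted p = 0.07), glycolysis (0.09, adjusted p = 0.07), histones (0.02, adjusted p = 0.91), histone deacetylases (0.01, adjusted p = 0.44) and ribosomal proteins (0.01, adjusted p = 0.97). Hexose transporters had a median of −0.01 but an upward mean (0.13), carried by HXT7 (1.23), HXT6 (1.10) and HXT4 (0.87), which stood at 0.68, 0.59 and 0.60 without chz1. HXT6 and HXT7 are near-identical, so the probes may not tell them apart. Amino acid synthesis had a median of 0.02 with a downward test.

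The preset test called 11 of 38 lists, and 8 of these in the same direction without the chz1 pair. With an estimated correlation 0 lists passed, and fry called 0 with a smallest adjusted p of 0.71. Adjusted over the list alone, 1 gene was called in all lists, CWP2 in the cell wall integrity list, whose median was 0.06 (adjusted p = 0.16). Proteasome (0.03) and phosphate genes (−0.05) turned when the untreated deletion was read as the reference.

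**Figure D3:**
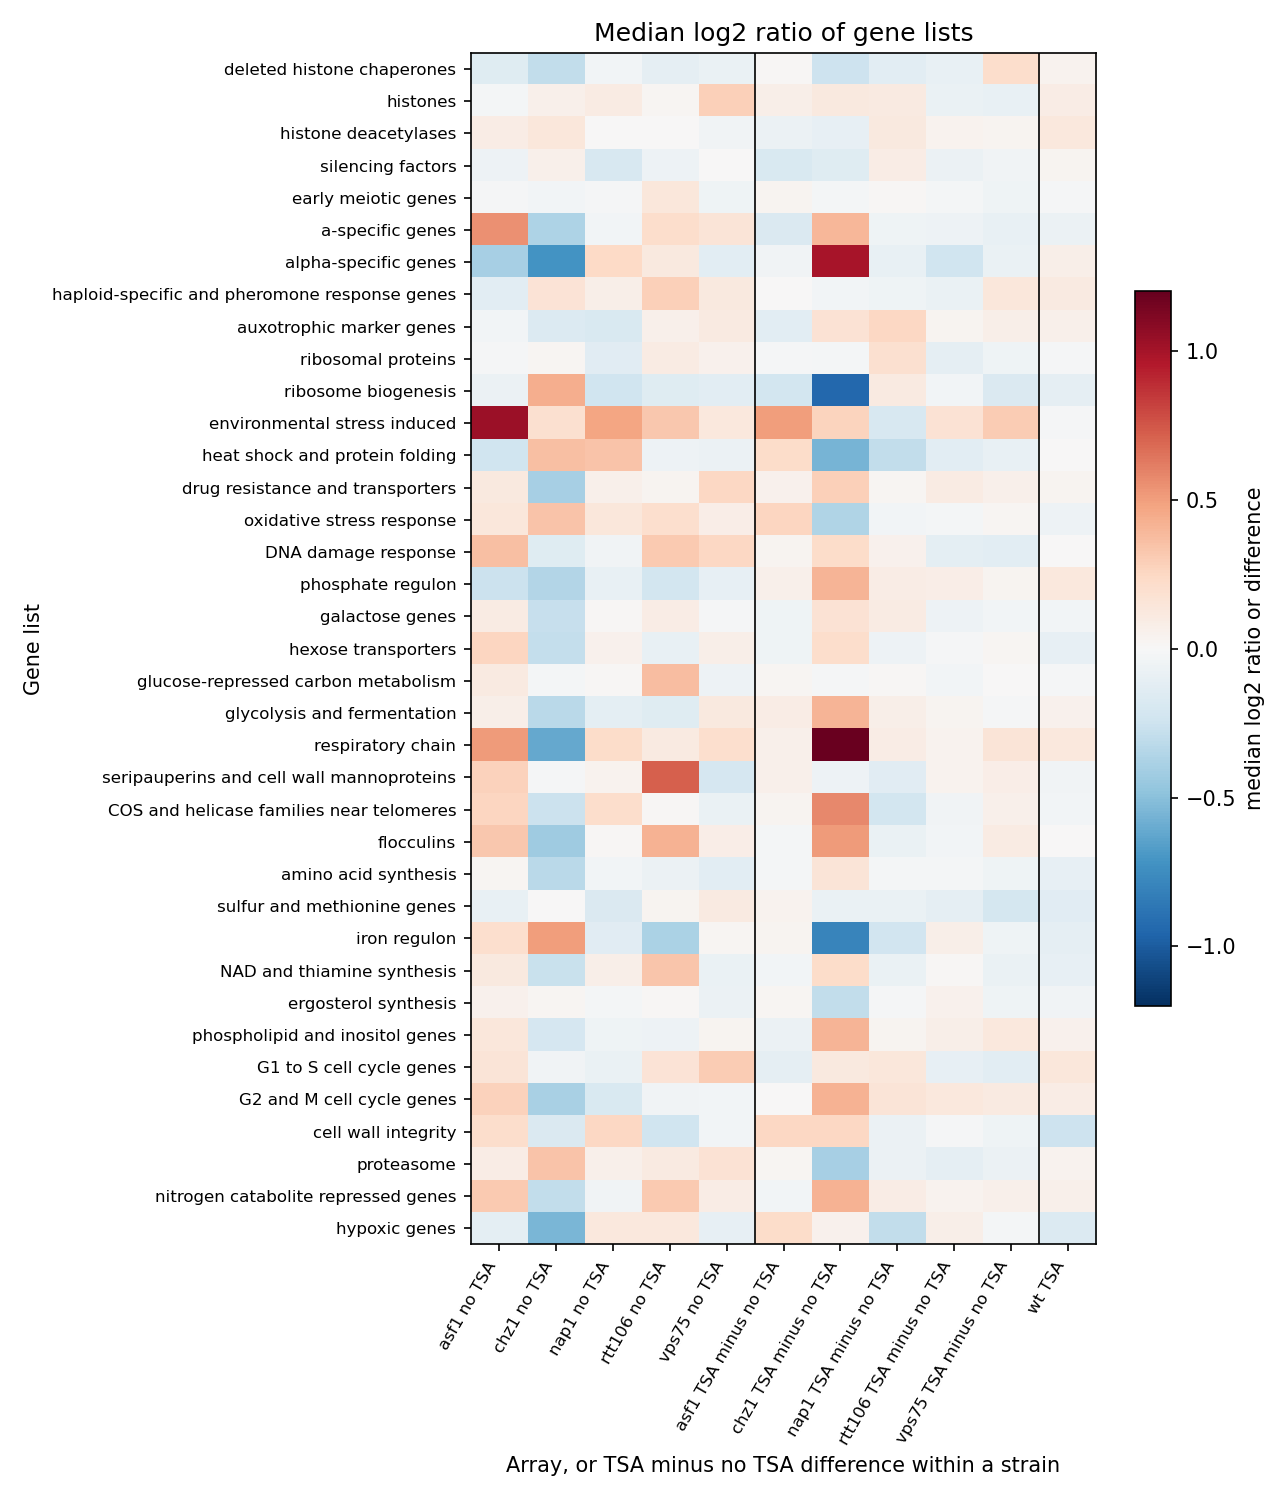
Median log2 value of gene lists (vertical axis) for each deletion without TSA, for TSA minus no TSA in each deletion strain, and for wild type with TSA (horizontal axis), on a colour scale from blue (lower) to red (higher). The TSA difference of the chz1 deletion reaches −0.94 for ribosome biogenesis and 1.19 for the respiratory chain.

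The loess step centres the ratios of each array near 0, so a change shared by most transcripts would not show. In wild type cells with TSA, relative to the other transcripts, 13 genes were at least 2-fold higher and 6 at least 2-fold lower on the 1 array. These counts depend on the processing, with 33 higher and 15 lower for normexp at offset 0 and 49 higher for the deposited log ratio. Among genes with a standard name that were detected in both channels, the lowest were the metalloreductase gene FRE1 (−1.68), REE1 (−1.40), NCW2 (−1.15), PRM7 (−1.05), the copper transporter gene CTR1 (−1.03) and IRC7 (−0.98). HAC1, which encodes the activator of the unfolded protein response, was highest among genes with a standard name at 2.57, followed by PSP2 (2.11), the ribosomal stalk gene RPP2A (2.04), LRO1 (1.69), the RNA helicase gene DHH1 (1.63) and HEM3 (1.56). With the array turned, whose direction is only likely, the highest and lowest genes would change places. The 6 highest belong to a group of 11 genes with a low signal in the reference channel of that array (median log2 deviation −1.69). On this array the reference channel carried 79.5% of the log2 ratios in the direction used here. Turned, it would carry 20.5% with each channel set against those of the same dye, and 30.8% against those of the same RNA. Cell wall integrity genes had a median of −0.25, at the 0 percentile of matched random lists, ribosome biogenesis −0.11 (0 percentile) and the respiratory chain 0.13 (99.8 percentile). Turned, these medians would change sign, and low and high percentiles would change places. Of the 254 genes at an unadjusted p under 0.05 in the deletions, 192 (75.6%) had the same sign in wild type, or 62 (24.4%) with that array turned, which would also turn the sign of the correlations below. Across genes, which are not independent replicates, the wild type ratios correlated with the mean TSA difference of the 5 deletions at r = 0.30 (rho 0.25), and at 0.46 when asf1 was left out. With that strain alone r was −0.45.

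The study's title concerns silencing near telomeres and the chaperone Chz1, so genes near chromosome ends were compared with all others. In the chz1 deletion without TSA, 70 of 306 detected subtelomeric genes (22.9%) were at least 1.5-fold lower, against 11.2% of other genes, and 15 were higher. An excess of lower genes was not particular to this array, with 6.6% against 0.8% in asf1 and 3.6% against 0.6% in vps75. Their median lay −0.179 below that of the other genes (95% bootstrap interval −0.245 to −0.056), the 0 percentile of matched random lists. The 5 outermost genes of each arm had a median of −0.24, the next 5 −0.13 and ranks 11 to 15 −0.019. With TSA the shift of the chz1 deletion was 0.019. In the rtt106 deletion without TSA the shift was upward, 0.109 (0.047 to 0.154), with 38 genes at least 1.5-fold higher (13.3%, against 3.6% of others), and it was 0.045 without families of near-identical genes. With TSA the rtt106 shift was 0.023, with 38 genes lower (13.8%, against 3.3% of others) and 26 higher. The chz1 shift was 0 with the series matrix, where rounding sets many values to 0. Shifts were 0.057 (0.012 to 0.116) for asf1, 0.03 (0.009 to 0.048) for nap1, −0.035 (−0.067 to −0.001) for vps75 and −0.034 (−0.056 to −0.01) for wild type with TSA. The wild type shift turned to 0.056 with median centring, 0.101 with the deposited log ratio and 0.138 with the series matrix, and that of vps75 to 0.008 with the deposited log ratio.

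The TSA difference of subtelomeric genes, relative to other genes, had a median of 0.14 in the chz1 deletion, 0.023 in asf1, −0.111 in nap1, −0.052 in rtt106 and −0.038 in vps75. The mean over strains was −0.008 (SD 0.095, n = 5), with 3 of 5 below 0 (exact two-sided sign-flip p = 0.8125, smallest possible 0.063), and −0.045 without chz1. The chz1 deletion lay 0.184 above the mean of the other 4, a comparison of 1 with 4 in which no exact two-sided p can go under 0.2. Over the alternatives this difference ranged from 0.022 to 0.346. Only IRC7 (−0.76 and −0.98) and the iron and copper transporter gene FET4 (−0.59 and −0.65) were at least 1.5-fold lower both in the chz1 deletion without TSA and in wild type with TSA. With the wild type array turned, 10 subtelomeric genes were lower there, and 9 of these were lower in the chz1 deletion too, where independent lists share 2.29. Their lowest values were those of YEL076C-A (−2.75 and −1.31) and YLR464W (−2.65 and −1.26). The TSA differences of this pair were close too, such as 2.88 and 2.77 in chz1 and −1.26 and −1.34 in rtt106. Genes of this group may be near-identical, so the probes may not tell them apart. They may then not be 9 separate measurements, and the expected 2.29 would not apply. As used, independent lists of 70 and 3 genes would share 0.69, and unchanged pairs simulated with a shared reference shared 1.95 on average. Across subtelomeric genes the ratios of these arrays correlated at r = −0.40 (0.40 with the array turned), with a covariance of −0.067 against 0.034 in the simulation. The chz1 array without TSA stood apart from all others in the spread of its log2 ratios, and 60.5% of these was carried by the reference channel, against 79.5% on the wild type array it is compared with here, or 20.5% to 30.8% with that array turned.

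**Figure D4:**
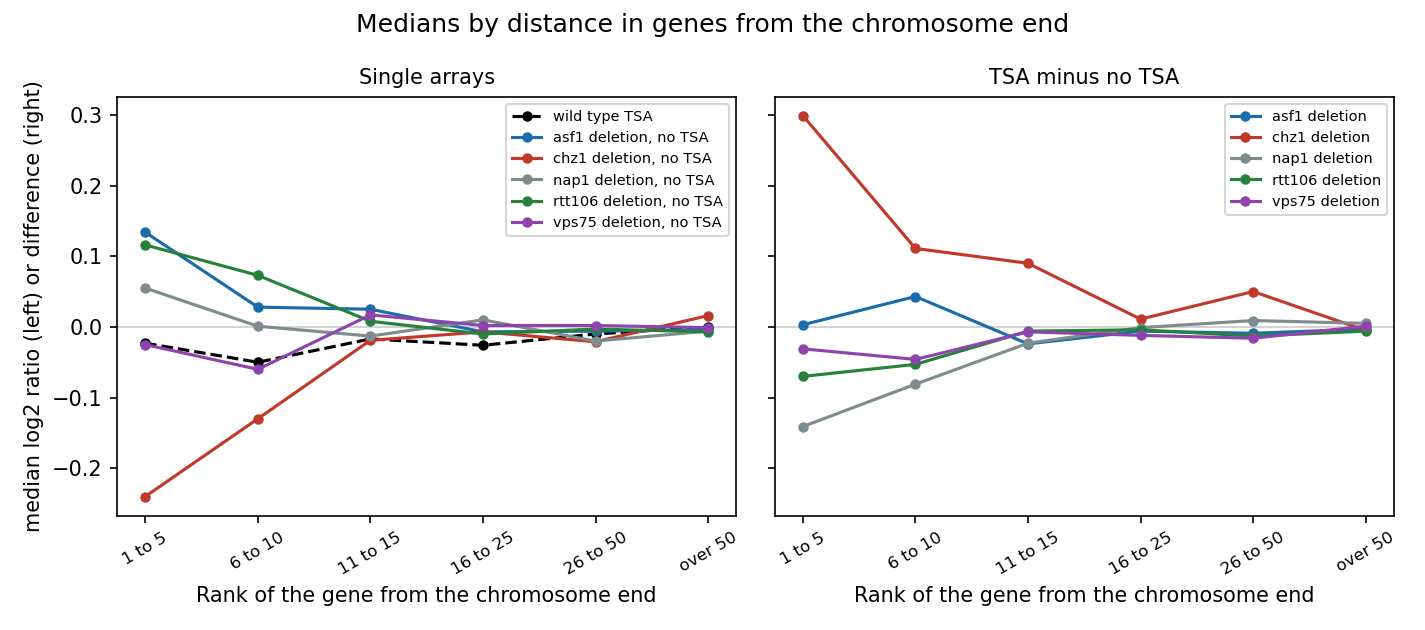
Median log2 ratio by gene rank from the chromosome end, on the left for the deletions without TSA and wild type with TSA, and on the right for TSA minus no TSA in each deletion strain. For ranks 1 to 5 the chz1 deletion has a median of −0.24 on the left and 0.299 on the right.

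Without TSA few genes passed 2-fold in nap1 (41 higher, 3 lower), rtt106 (63 and 14) and vps75 (55 and 15), more in asf1 (104 and 7) and most in chz1 (132 and 252). This order depends on the scaling, since with scale normalization between arrays chz1 had 26 genes beyond 2-fold, nap1 79 and vps75 228. No gene of 6035 passed 2-fold the same way on all 5 arrays. The following ranks, for all 5 deletions, are among genes with a standard name that were detected in both channels. The asf1 deletion had the stress genes HSP12 (4.51), YGP1 (3.76) and DDR2 (3.30) highest. Apart from ASF1 (−4.47), the acid phosphatase genes PHO12 (−1.73) and PHO11 (−1.53) and PAU20 (−1.47) were lowest. In the chz1 deletion TMA10 (4.03), EGO4 (3.10) and BTN2 (3.09) were highest, and after CHZ1 the decarboxylase gene ARO10 (−2.81) and the weak acid pump gene PDR12 (−2.80) were lowest. With TSA the same strain had 1.22 for TMA10, 0.40 for EGO4, −1.17 for BTN2, 1.25 for ARO10 and 0.37 for PDR12. The nap1 deletion showed HSP42 (3.02), the polyamine transporter gene TPO2 (2.74) and CMK2 (2.67) at the top, and the phosphate transporter gene PHO89 (−1.39) and RRN11 (−0.92) after NAP1 at the bottom.

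In the rtt106 deletion the NAD synthesis gene BNA2 (2.67), the DNA damage marker HUG1 (2.24) and the chitin deacetylase gene CDA1 (2.20) were highest. Apart from RTT106 (−3.25), the fatty acid desaturase gene OLE1 (−2.07), mitochondrial cytochrome b COB (−1.97) and PLB2 (−1.41) were lowest. In the vps75 deletion HSP26 (1.95), ARO10 (1.86) and COX5B (1.68) were highest, and, apart from VPS75 (−3.94), PHO89 (−1.87), OLE1 (−1.41) and PHO5 (−1.40) lowest. Stress-induced genes had a median of 1.03 in asf1, 0.47 in nap1 and 0.32 in rtt106, each at the 100 percentile of matched random lists. Respiratory chain genes stood at 0.51 in asf1 and −0.61 in chz1, the 100 and 0 percentiles. On these single arrays dye effects were not removed.

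Contrasts of each deletion with the mean of the other 4, over both arrays of a strain, showed a stress and DNA damage profile in the asf1 deletion. HSP12 was 3.69 higher (SE 0.52, adjusted p = 0.022), YGP1 3.45 higher (SE 0.30, adjusted p = 0.0043) and DDR2 3.14 higher (SE 0.25, adjusted p = 0.0034), in each case on both arrays. Of 50 stress-induced genes 14 rose, or 35 adjusted over the list alone, and the list median was 0.78 (preset adjusted p = 5e-21, adjusted p = 0.36 with an estimated correlation). Among 22 DNA damage genes HUG1 (3.06) and the ribonucleotide reductase genes RNR2 (1.56), RNR3 (1.46) and RNR4 (0.95) rose, with 12 higher adjusted over the list alone (median 0.38, preset adjusted p = 4.8e-07, adjusted p = 0.36 with an estimated correlation). Of 25 cell wall genes PIR3 (2.65), GSC2 (1.46), HSP150 (1.10), KTR2 (0.77) and CRH1 (0.60) rose, 10 adjusted over the list alone (preset adjusted p = 2.4e-06, adjusted p = 0.36 with an estimated correlation).

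Mating genes went apart in the same strain. The a-factor genes MFA1 (0.98) and MFA2 (0.94) rose, 4 of 5 a-specific genes adjusted over the list alone, although BY4742 is an alpha strain (median 0.54, preset adjusted p = 0.0096, adjusted p = 0.36 with an estimated correlation). Haploid and pheromone response genes had a median of −0.26 (preset adjusted p = 2.5e-06, adjusted p = 0.36 with an estimated correlation), with FUS1 lower by a log2 of −0.78 and 6 lower adjusted over the list alone. The histone genes HTA2 (−0.83) and HTB2 (−0.78) fell. PHO12 (−0.98, SE 0.10, adjusted p = 0.0094), PHO11 (−0.93) and SPL2 (−0.70) fell, while the thiamine-regulated phosphatase gene PHO3 (1.36) rose. PAU20 fell as well (−1.11, SE 0.19, adjusted p = 0.035), and the siderophore retention genes FIT2 (1.72) and FIT3 rose. In all, limma called 98 genes higher and 18 lower in asf1, a count of 116 that ranged from 14 without vps75 to 711 without chz1. It was 34 without nap1 and 67 without rtt106.

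The rtt106 deletion differed most in seripauperin and related cell wall genes, of which 16 of 30 rose and 0 fell (23 adjusted over the list alone). Examples were PAU5 (1.28), TIR1 (1.22) and PAU3 (1.05), and the list median was 0.71 (preset adjusted p = 5.6e-23, adjusted p = 0.12 with an estimated correlation). Members of this family are near-identical, so the probes may not tell them apart. NAD and thiamine genes followed, 7 of 31 higher (17 adjusted over the list alone), with BNA2 at 2.46 (SE 0.25, adjusted p = 0.0041), BNA4 at 1.56, BNA1 at 1.53 and THI73 at 1.31 (preset adjusted p = 2.4e-11, adjusted p = 0.12 with an estimated correlation). Genes that glucose represses were higher in 5 of 33 cases (15 adjusted over the list alone), among them ADH2 (1.39), the lactate transporter gene JEN1 (1.29) and malate synthase MLS1 (0.92), with a preset adjusted p of 2.1e-08 and adjusted p = 0.11 with an estimated correlation. PHO92 (1.92, SE 0.14, adjusted p = 0.0014), CDA1 (1.86, SE 0.13, adjusted p = 0.0012), HXT9 (1.45), PRM2 (0.96) and the meiotic gene RED1 (1.11) also rose. COB (−2.60, SE 0.32, adjusted p = 0.0086), FIT3 (−1.43, SE 0.23, adjusted p = 0.023) and the early meiotic activator IME1 (−0.69) fell. The contrast called 120 genes higher and 14 lower, 134 in all, with 51 when vps75 was left out, 66 without nap1 and 859 without chz1.

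In the vps75 deletion SIM1 (1.31, SE 0.17, adjusted p = 0.0066) and the RNase P subunit gene RPR2 (1.30, SE 0.17, adjusted p = 0.0073) rose. HUG1 (−1.68, SE 0.27, adjusted p = 0.019) and BNA2 (−1.38, SE 0.25, adjusted p = 0.031) were called lower against the other 4, with ratios of only −0.45 and −0.40, and −0.50 and −0.60, in vps75 itself. Drug transporter genes PDR15 (0.99), QDR1 (0.95), RSB1 (0.83) and PDR5 (0.70, own ratios 0.30 and 0.00) were called higher, 4 of 22, the same number adjusted over the list alone (preset adjusted p = 0.0049, adjusted p = 0.66 with an estimated correlation). Of 137 ribosomal protein genes 5 rose, among them RPL34B (0.98), RPL40A (0.93) and RPL2B (0.91). The serine synthesis gene SER33 (1.11), the lysine synthesis genes LYS12 (1.01) and LYS1 (0.86), and HTB2 (0.63) rose too. The seripauperin list (median −0.31, preset adjusted p = 4.9e-12) and the NAD and thiamine list (−0.20, preset adjusted p = 2e-08) stood lower, both lost with adjusted p = 0.26 with an estimated correlation. Their own medians on the vps75 array without TSA were −0.20 and −0.08, and the mean they are set against holds the rtt106 strain, with 0.72 and 0.33 on that array. The telomere-proximal genes COS8 (−0.99) and COS12 (−0.92) fell, as did the alpha-factor gene MF(ALPHA)2 (−1.0). There were 140 genes higher and 35 lower, and 545 in all without chz1.

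The nap1 contrast called PHO11 higher (0.91, SE 0.09, adjusted p = 0.043), although its own ratios were −0.04 and −0.02, and NAP1 lower, 2 genes, with 537 at an unadjusted p under 0.05, and 443 called without the chz1 pair. The chz1 contrast called 3 genes higher and 14 lower. PHO11 was called 0.67 higher (SE 0.09, adjusted p = 0.045) with own ratios of −0.20 and −0.25. Both calls come from lower values elsewhere, such as −1.53 and −1.47 in asf1. After CHZ1 (−3.50) the lowest were BNA2 (−2.14, SE 0.25, adjusted p = 0.041) and BNA1 (−1.55, SE 0.13, adjusted p = 0.015). LYS1 (−1.12), the allantoinase gene DAL1 (−0.92) and RNR3 (−0.80) were called lower too, with own ratios of −0.63 and −0.34, −0.12 and −0.65, and 0.04 and −0.29. Of the NAD and thiamine list 12 genes were lower adjusted over the list alone (median −0.24, preset adjusted p = 3.1e-06, adjusted p = 0.22 with an estimated correlation). Other deleted chaperone genes came out higher in several contrasts, such as VPS75 (0.92) in chz1, because their own deletions lower the mean they are set against. The same construction touches all genes called in opposite directions in different strains, among those named here PHO11, PHO92, BNA1, BNA2, HUG1, HTB2, COS8, RNR3, DAL1, LYS1, PIR3, KTR2, CDA1, PGM2, PDR5 and FIT3, so a rise or fall of these in 1 strain may rest on another strain, and the same holds for list medians of the contrasts. HTB2 in vps75, for example, had ratios of 0.45 and 0.21, against −0.82 and −0.77 in asf1. The chz1 count was 0 without asf1.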

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

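Of the tests in this part, the correlation between the chz1 arrays, the CHZ1 level and the interaction without the chz1 pair were chosen after the result was seen, whereas the test of the reference channel and the splits were not.

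The array of the chz1 deletion without TSA stood apart from the other arrays in its log2 ratios. It had 384 genes beyond 2-fold and an SD of its log2 ratios of 0.542, the highest among the 5 arrays without TSA. The SD of the TSA difference in the chz1 strain was 0.661, against 0.255 for asf1, 0.237 for nap1, 0.182 for rtt106 and 0.205 for vps75. Each of these 3 values was farther from the other strains than Dixon's test allows at 95%, among 7 groups checked, and chance alone marks about 1 in 20 groups. The TSA effect of the chz1 strain differed from that of the other 4 strains for 1769 genes (945 higher, 824 lower, limma interaction). For the other strains it found 0, but the spread then included the chz1 pair. Without that pair it found 8 genes for asf1, 18 for nap1, 0 for rtt106 (39 at an unadjusted p under 0.05) and 0 for vps75 (82). These tests had 3 and 2 residual degrees of freedom and assumed that the lone strain varies like the others. The SD of 0.661 goes against that assumption for chz1, so the count of 1769 is no reliable test.

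A wrong strain is argued against, since CHZ1 stood at −2.86 on this array. A chz1 effect that TSA leaves in place did not show, since the 2 arrays of the strain correlated at r = −0.15 across genes, where the other strains had 0.45 to 0.86. Another reference RNA could lower this r as well, so it cannot decide on such an effect. The reference RNA of the array is a candidate explanation, since the reference channel carried 60.5% of its log2 ratios, against 5.0% to 37.1% on the other deletion arrays and 79.5% on the wild type array, or 20.5% to 30.8% with that array turned, whose direction is only likely. The labels of the chz1 array without TSA disagree on its reference, although CHZ1 had a signal of 3767.5 in that channel. The file of the chz1 array without TSA also had 20 columns where the others had 24, and 18 control probes where the others had 0, so another batch of hybridization remained open. So did a deletion effect that TSA reverses and a different growth state of the cultures, and none of these was tested. All TSA differences of the chz1 strain rest on this array. In its separate channels the nap1 array without TSA, which was turned, stood farther apart. Its reference channel correlated with the other references at r = 0.816, against 0.929 for chz1 without TSA and at least 0.986 elsewhere. Its channel deviations had SDs of 1.07 (reference) and 1.10, against 0.70 and 0.63 for chz1. Dixon's test did not mark that r, the cause was not tested, and all nap1 TSA differences rest on that array.

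Other divisions of the 10 arrays were set against the division by TSA. Of 100 splits into 5 and 5, drawn with the real one included, 35 gave at least as many genes at an unadjusted p under 0.05 as the real 254, and the highest other gave 2727. For gene lists 48 of 100 gave as many as the real 11, with 15 as the highest other. With strain as a block, a split that parts only 1 or 3 strains rests on fewer pairs, and many drawn splits repeat the same fit. These shares therefore do not measure chance for the comparison over all 5 strains. The 4 splits that parted only the chz1 arrays gave 2727 genes, of which 2083 were called, which points to a structure of the samples. With strain as a block these 4 are the same fit of the chz1 pair, so they restate its difference and add no evidence. All other drawn splits gave at most 812 genes, with 0 called. At most 2 genes were called, in splits that gave 139. When TSA and no TSA were exchanged within strains, 4 of 16 arrangements gave as many genes (highest 382) and 8 as many lists (highest 13). These arrangements part all 5 strains, as the real one does. The real one is counted, so the smallest possible share is 1 of 16. Chance could not be excluded for genes or lists.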

How the results depend on the processing

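Counts, shifts, gene lists and the genes named for TSA and single arrays were recomputed with 1 choice changed at a time, except that the series matrix also exchanges the vps75 arrays, that the wild type array was added with the chz1 pair left out, and that the contrasts against 0 had wild type TSA in the fit. Single genes of the strain contrasts were not recomputed. Of the alternatives, normexp with offset 50, the deposited log ratio, exchanged vps75 arrays, a turned wild type array, other numbers of outermost genes and the wild type array added with the chz1 pair left out were chosen after seeing the data. For the 24 named genes of the TSA comparison, 482 of 503 values kept direction and side of the threshold, 20 newly passed it and 1 reversed. For the 11 gene lists, 187 of 242 values were the same, 51 no longer passed and 4 reversed in the direction of the test. Of the 504 values of genes named on single arrays 152 were the same and 352 moved, and of 371 counts and shifts 240 were the same and 131 moved. The fit with no replicate block (strain left out) changed no call of a single gene and gave 12 lists in place of 11. Not run were the probe with the highest intensity, since each gene had 1 probe, distances in kilobases, since no coordinates were used, and the scanner's own log ratio, which the files did not hold. Signal over background limits the dim genes, and on the asf1 array with TSA the floor of the experimental channel was 131.25, the highest of all arrays. Except where the construction of an alternative shows it, the cause was not tested.

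At 1.5-fold, wild type with TSA had 58 genes higher and 32 lower, and the deletions had 334 (asf1), 1313 (chz1), 149 (nap1), 322 (rtt106) and 269 (vps75) beyond the threshold. At 3-fold these were 6 and 1, then 33, 93, 17, 14 and 6, fewer by construction. With no background correction wild type had 26 higher and 11 lower, and chz1 had 714, rtt106 148 and vps75 107 beyond 2-fold. The subtelomeric shift was then −0.06 in wild type and −0.252 in chz1, and the TSA shift of chz1 minus the others was 0.298. With normexp at offset 0 the counts were 33 and 15 in wild type, then 215 (asf1), 738 (chz1), 75 (nap1), 204 (rtt106) and 124 (vps75), the shifts −0.061 (wild type), −0.255 (chz1) and 0.051 (nap1), and chz1 minus the others 0.325. With normexp at offset 50 the nap1 contrast called 4 genes.

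With median centring the asf1 contrast called 177 genes and that of rtt106 81, and the shifts were 0.056 (wild type), 0.141 (asf1), 0.061 (nap1) and 0.214 (rtt106). With scale normalization between arrays wild type had 28 higher and 15 lower, chz1 had 26, nap1 79 and vps75 228 beyond 2-fold, and the contrasts called 5 (chz1), 21 (nap1) and 289 (vps75). With the series matrix 49 genes were higher in wild type, and 286 (asf1), 788 (chz1), 74 (nap1), 335 (rtt106) and 193 (vps75) passed 2-fold. The contrasts called 197 (asf1), 10 (chz1) and 53 (rtt106). Its shifts were 0.138 in wild type, asf1 and nap1, 0.263 in rtt106 and 0 in chz1 and vps75, where rounding sets many values to 0, and the mean TSA shift was 0.096. The list test turned downward for the stress list, although its median stayed above 0 (0.04), and the sulfur and methionine list reversed (0.03). With the deposited log ratio 49 genes were higher in wild type, 286 (asf1), 788 (chz1), 74 (nap1), 335 (rtt106) and 119 (vps75) passed 2-fold, the contrasts called 249 (asf1), 38 (chz1) and 78 (rtt106), and the shifts were 0.101 (wild type), 0.185 (asf1), 0.118 (nap1), 0.268 (rtt106) and 0.008 (vps75).

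With only genes above the floor in both channels on every array, the contrasts called 5 (chz1), 0 (nap1) and 48 (rtt106). With trend and robust variance they called 76 (asf1), 3 (chz1) and 0 (nap1). Against 0 with wild type TSA in the fit they called 324 (asf1), 1 (chz1), 1 (nap1) and 259 (rtt106). Leaving out 1 strain in turn gave 14 to 711 for asf1, 0 to 7 for chz1, 0 to 443 for nap1, 51 to 859 for rtt106 and 122 to 545 for vps75. An estimated correlation and fry each left 0 lists. With the untreated deletion read as the reference, limma called 202 genes higher and 206 lower under TSA, chz1 minus the others was 0.022, and NCE103 (0.02), phosphate genes (−0.05) and proteasome genes (0.03) reversed.

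With means the shifts were 0.011 (asf1), −0.088 (vps75) and −0.007 (wild type), and chz1 minus the others 0.315. Without near-identical families rtt106 stood at 0.045 and chz1 minus the others at 0.31. These families were recognized by standard names, so genes without one stayed in. With 5 outermost genes asf1 stood at 0.138 and chz1 minus the others at 0.346, and with 25 rtt106 at 0.025, vps75 at −0.001 and chz1 minus the others at 0.094. Without the turn of the nap1 array the contrasts called 3 (chz1) and 7 (nap1), and the nap1 shift was −0.03. With the vps75 arrays exchanged, 113 genes passed 2-fold in vps75, its shift was −0.102 and the contrasts called 8 (chz1) and 1 (nap1). With the wild type array turned it had 6 genes higher and 13 lower and a shift of 0.034, by construction. With wild type added and the chz1 pair left out limma called 3 genes higher under TSA.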

Other observations

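The tests of the mirrored genes and of the copper genes were chosen after the result was seen.

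The vps75 deletion without TSA had raised medians of the genes that act between G1 and S phase (0.30, the 100 percentile of matched random lists) and of histones (0.29, the 99.96 percentile). DNA damage genes stood at 0.25 and proteasome genes at 0.17 on the same array, both at the 100 percentile. In the contrast of vps75 with the other deletions the medians were 0.17 for G1 to S genes and 0.19 for histones. DNA damage genes had −0.02 and proteasome genes 0.03 there, so the contrast did not show their rise. In the asf1 deletion the phosphate regulon had a median of −0.26, at the 0 percentile, and genes of G2 and M 0.28, at the 100 percentile. The chz1 deletion without TSA had hypoxic genes at −0.55 and amino acid synthesis at −0.32, both at the 0 percentile, and the iron regulon at 0.50 and ribosome biogenesis at 0.44, both at the 100 percentile. In the rtt106 deletion the iron regulon stood at −0.38 (0 percentile) and haploid and pheromone response genes at 0.29 (100 percentile). The percentiles are of single arrays with no test, on which dye effects were not removed.

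Among the histone deacetylase genes, HOS2 had a mean TSA difference of 0.52 and HST3, which encodes a sirtuin, a class that TSA does not inhibit, of 0.42. Without the chz1 pair these were 0.36 and 0.18, and in wild type cells 0.87 and 0.47. The a-specific genes MFA2 and BAR1, which encodes the protease that degrades alpha-factor, had means of 0.31 and −0.23. The drug transporter genes TPO2 and PDR12 averaged 0.74 and 0.73, with 2.24 and 3.17 in the chz1 strain and means of 0.37 and 0.12 without it. None of these genes passed the adjustment.

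Copper uptake genes, the targets CTR1, CTR3, FRE1, FRE7, REE1 and IRC7 of the copper-sensing activator Mac1, had median TSA differences of −0.35 in asf1, −1.59 in chz1, −0.59 in nap1, −0.70 in rtt106 and −1.10 in vps75, and a median ratio of −1.0 in wild type, although they were chosen because most of them were low. The chz1 array without TSA cannot alone be the source of the whole pattern, since it does not enter the differences of the other deletions. Those lay below 0 too, although most of the genes were chosen for low values. The wild type array adds to this only if the direction used for it holds. That array does not hold the chz1 array and took no part in the comparison that named 5 of the 6 genes. On it 0 of 10000 random lists of 6 genes had a median as far from 0 in either direction, but random lists lack a shared regulator. The list was also written after this array was seen, where FRE1, REE1, CTR1 and IRC7 were among the 6 lowest named genes. The count is therefore no independent test. Turned, the wild type array would have the copper uptake genes higher, against the pattern. Against the other arrays, its treated channel stood at −0.04 and its reference channel at 0.41 for these genes. This reference value was ordinary, since those of the other arrays lay between 0.23 and 0.44, apart from chz1 and nap1 without TSA. A dye or reference effect equal on every array cancels in the difference within a strain, so it cannot give the TSA differences of the deletions. It stayed open as a part of the wild type ratio, which is no difference between arrays. The medians on arrays without (−0.27) and with TSA (−0.97) add nothing to this, since the genes were chosen for that difference of 0.71. Differing reference RNA stayed open for part of the pattern, since the reference channel was low on the chz1 and nap1 arrays without TSA (−1.41 and −1.32) and the experimental channel was not lower with TSA in these strains (−0.46 without and −0.30 with TSA in chz1, −0.72 and 0.08 in nap1). The experimental channel was lower with TSA in asf1 (0.68 without and 0.31 with TSA), rtt106 (0.72 and −0.17) and vps75 (0.65 and −0.66). The reference channel of these 3 strains lay between 0.23 and 0.36 throughout. More copper sensed by the cells stayed open, since the detoxification genes CUP1-1, CUP1-2, CRS5 and SOD1 had a median above 0 in 3 of 6 strains with members going both ways, and a TSA response through Mac1 or chromatin was not tested.

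Of the 13 genes at least 2-fold higher on the wild type array and the 17 at least 2-fold lower under TSA in the asf1 deletion, 11 were shared, where independent lists share 0.04. YEL076C-A and YLR464W among these 11 may not be separate measurements. The shared genes with a standard name were HAC1, PSP2, RPP2A, LRO1, DHH1, HEM3 and CPS1. As used, the treated channel of the wild type array was raised by only 20.5% of the median log2 ratio of the 11 genes, 1.63, and its reference channel was lower by a median of −1.69, which is 103.9% of it. With the array turned the treated channel would be the low one (−1.69 against the same dye, −1.38 against the same RNA), as on the asf1 array with TSA (−1.54). The direction was not settled by r = 0.46 between that array and the other 4 deletions, since r with asf1 was −0.45 (−0.46 and 0.45 turned), so exchanged channels, a TSA response of these cells and the reference RNA of the array all stayed open.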
